A study of Mus musculus with 6 samples.

How the data were processed

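RNA of naive CD8 T cells from the spleens of 3 wild type and 3 LAIR-1-deficient mice was measured in 6 libraries. Per the labels' protocols, spleens were dispersed, red blood cells were lysed, and 100000 naive CD8 T cells per mouse were sorted into TRIzol. Libraries were made from total RNA with Illumina TruSeq small RNA primers, per the labels' protocols. The deposited values are raw counts per gene, as whole numbers in 1 column per library, per the file headers and the values. The submitters' processing notes name BWA, with no version, and the genome build mm10. The gene annotation, the counting tool, the strand setting and any use of molecular identifiers are not given in the sources used here. Overlapping, antisense and near-identical genes therefore cannot be told apart by these counts, and intervals from counts cover counting error only.

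Columns were matched to samples by the sample descriptions, and groups and mouse numbers were taken from the sample titles. The table held 14515 gene rows with no repeated symbol, and 4 spike-in rows that had 0 to 4 counts per library and were left out. Rows are named by symbol and chromosome; 14327 matched 1 gene of GENCODE vM21 (GRCm38), 750 of them through an older symbol, and 188 did not match and were kept under their own symbol. Coordinates are from that annotation. Library totals over genes ranged from 5519748 to 9187017. A chi-square test of counts between each pair of libraries, over genes with a summed count of at least 50, gave between 5.39 and 26.1 per gene where sampling noise gives about 1. No 2 libraries agreed within sampling noise, and all 6 were used as separate mice.

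Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr at its default smallest count of 10, libraries were scaled by TMM, and LAIR-1-deficient was compared with wild type with a robust quasi-likelihood F test, two-sided, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 9565 genes tested, with a threshold of 0.05. The SE of a log2 fold change was derived from the fold change and the F statistic. Common biological variation was 0.135. The 95% interval of the ratio of Lair1 counts was computed from the summed counts and scaled library sizes by the exact binomial method.

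Gene lists, the main tests and the rule for naming genes were fixed before the data were examined, except for the pattern of mitochondrially encoded genes. Additions to the planned tests were the permutation tests of list medians, the binomial interval of Lair1 and the share of Malat1. Lists covered T cell states, signalling, interferon, stress and metabolism, markers of other cell types and technical sets. Older symbols in the table were matched to list members by synonym. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists tested. Camera with an estimated correlation and fry were run beside it, and Lair1 was in no list. The pattern of mitochondrially encoded genes was widened, after the table was seen, to all 37 genes on the mitochondrial chromosome, because the table writes the protein-coding ones without a hyphen. The pattern for T cell receptor variable segments matched no gene of the table, and the pattern for immunoglobulin segments matched only Ighmbp2, which is not a segment and was left out, so these sets were not analysed here. Per-library values of a list are medians of log2 CPM after subtracting each gene's mean over the 6 libraries. Shares of counts and list medians were compared by exact permutation tests, two-sided.

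The text names Lair1 and the genes of the sorting gate, and then the 8 genes per direction with the largest fold among those that passed with no overlap between groups. Where fewer passed, it names all that passed and the genes with the smallest unadjusted p up to 8, said not to pass. It also names, per functional list, the 2 tested members with the smallest unadjusted p and, per other cell type, the 2 most abundant tested members, or the most abundant members where none was tested. Gene models without a symbol are not named, and 1 gene of the sorting gate is not reported here. Genes named outside this rule are said to be chosen after their values were seen. Exceptions are the sex-linked genes Xist and Ddx3y and genes called only in other fits or splits.

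The scripts were tested on simulated counts for the 9565 genes tested, drawn from the real means, dispersions and library sizes in 5 runs with 200 genes changed in each. A 1.5-fold change was recovered in 38.2%, a 2-fold change in 80.9% and a 4-fold change in 99.1% of changed genes, with 54 false calls in all runs together. The true fold lay inside the 95% interval for 95.2% of genes. A list shifted by 1.25-fold was called in 5 of 5 runs, and 3 other list calls were made. Simulated genes varied independently of each other, so list calls under correlation between genes were not tested.

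Alternatives planned before the data were examined were other scalings (RLE size factors, upper quartile, library totals), no filter or a smallest count of 50, DESeq2 1.42.0, limma-voom with and without quality weights, edgeR without robust estimation, the mouse number as a block, leaving out each library in turn, leaving out mitochondrially encoded genes, and other windows around Lair1. Leaving out mouse 1 of both groups was added after the data were seen. Tables were joined and figures drawn with Python 3.11.15.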

Results

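The comparison asks whether loss of LAIR-1 changes the transcriptome of resting naive CD8 T cells. LAIR-1 is an inhibitory receptor of leukocytes that binds collagen and is encoded by Lair1. Spleens were taken from 3 wild type and 3 LAIR-1-deficient mice. From each spleen, 100000 naive CD8 T cells were sorted by surface proteins that included CD45, CD3, CD8 and absence of CD44, and their total RNA was sequenced as 1 library per mouse. The counts assigned to genes summed to 7974206, 9187017 and 8939919 in wild type mice 1 to 3. They summed to 7039990, 5519748 and 7296424 in LAIR-1-deficient mice 1 to 3, so all LAIR-1-deficient libraries were shallower than all wild type libraries. Between 11863 and 12554 of the 14515 genes in the table had a count in a given library. Levels below are counts scaled to library size with TMM factors (CPM, as computed by edgeR), given as mean ± SD over the 3 libraries of a group, and fold changes are LAIR-1-deficient over wild type.

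Lair1 itself was nearly absent from the LAIR-1-deficient libraries. It had 58, 32 and 43 counts in the wild type libraries and 2, 1 and 1 in the LAIR-1-deficient libraries, or 133 against 4 in sum. Its level was 5.21 ± 1.94 CPM in wild type and 0.201 ± 0.0784 CPM in LAIR-1-deficient cells (SD, n = 3 each). By counts, the LAIR-1-deficient level was 3.93% of wild type (95% interval 1.06 to 10.3%), a 25.4-fold difference (9.70 to 94.7), with intervals that cover counting error only. In edgeR's quasi-likelihood test the log2 fold change was -4.58 with an SE of 0.57 and an adjusted p of 0.00255. The gene (ENSMUSG00000055541.17) lies on the minus strand of chromosome 7 from 4003402 to 4063204 in GRCm38 and is annotated as protein coding, with 7 exons in its transcript Lair1-201. The part of the gene that the allele removes is not given in the labels, nor is the part that the reads cover. The counts are therefore those assigned to the gene, wherever in it they fall. Without wild type mouse 1, whose library had the highest level, the adjusted p was 0.0592 at a log2 fold change of -4.26. Under limma-voom the log2 fold change was -4.20 with an adjusted p of 0.142.

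Genes of surface proteins used for sorting were close to equal in both genotypes. Cd8a, a chain of the CD8 coreceptor, was at 925 ± 60.3 CPM in wild type and 939 ± 42.2 CPM in LAIR-1-deficient cells, and Cd8b1, its partner chain, at 1516 ± 55.8 and 1478 ± 28.9 CPM. Ptprc, which encodes CD45, was at 605 ± 94.9 and 594 ± 76.4 CPM. Cd3e, Cd3d and Cd3g had log2 fold changes of -0.01, -0.02 and 0.04. Cd44, whose protein was gated out, was low in both groups, at 12.5 ± 0.578 and 15.9 ± 5.37 CPM, with a log2 fold change of 0.34 and a 95% interval of -0.10 to 0.79. Its level was 21.8 CPM in LAIR-1-deficient mouse 1 and 14.8 and 11.2 CPM in the other LAIR-1-deficient mice, and without LAIR-1-deficient mouse 1 the log2 fold change was 0.04. None of these genes passed the test.

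**Figure D1:**
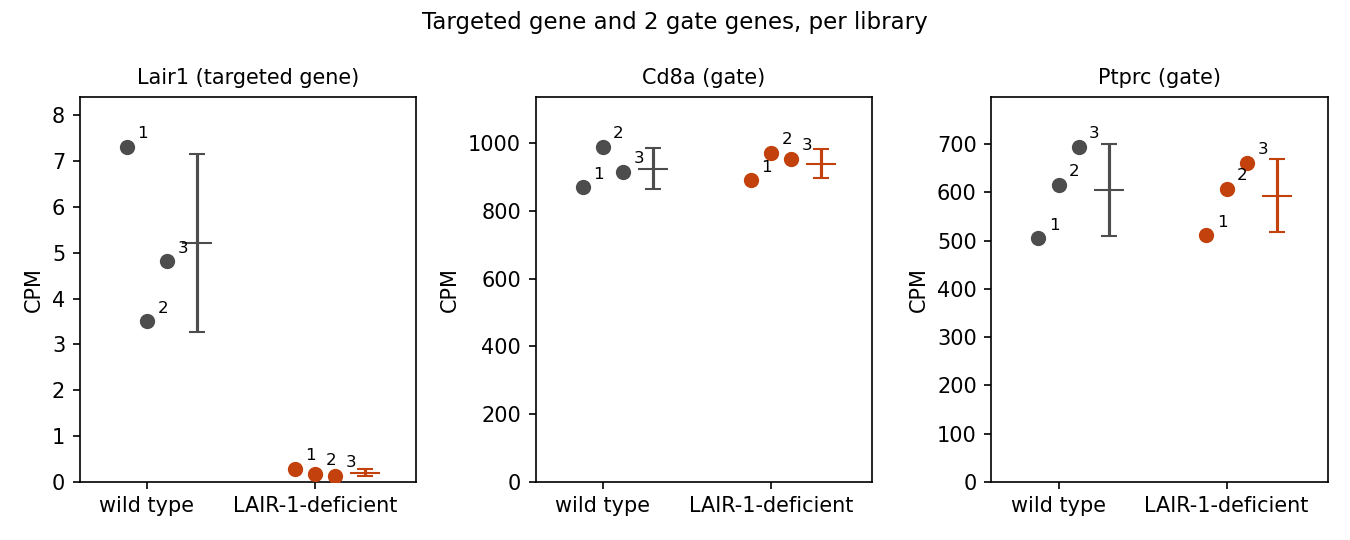
Scaled counts (CPM, vertical axes, from 0) of Lair1, Cd8a and Ptprc in each library; points are mice, numbered as in the labels, and the bars beside them are the mean and SD of the 3 libraries of a group. Lair1 lies between 3.50 and 7.32 CPM in the wild type libraries and between 0.137 and 0.288 CPM in the LAIR-1-deficient libraries, while the groups overlap for both gate genes.

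Beyond Lair1, no gene was called different between the genotypes. Of 9565 genes tested, edgeR called 0 higher and 1 lower in LAIR-1-deficient cells at an adjusted p under 0.05, and that gene was Lair1. The second smallest adjusted p was 0.9999. An unadjusted p under 0.05 was reached by 311 genes (3.25%), of which 173 were higher and 138 lower, where 478 are expected by chance. DESeq2 also called 0 higher and 1 lower. limma-voom called 0 in either direction, with 302 genes at an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 802 genes (8.39%), while chance gives 10%.

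The genes with the smallest p in the higher direction, none of which passed, had small fold changes. Bcl9l, a coactivator of beta-catenin, was at 174 ± 4.42 CPM in wild type and 254 ± 46.2 CPM in LAIR-1-deficient cells, a log2 fold change of 0.54 with a 95% interval of 0.30 to 0.79. It passed the edgeR test (1 gene higher) when no low-count filter was used or when LAIR-1-deficient mouse 3 was left out. Med24, a subunit of the Mediator complex, went from 34.5 ± 2.04 to 49.0 ± 3.51 CPM, and Mrps2, a mitochondrial ribosomal protein, from 36.7 ± 4.59 to 52.9 ± 6.92 CPM. The complex I subunit gene Ndufb5 had means of 133 ± 9.17 and 169 ± 11.7 CPM. Antxr2, Coro2a, Usp10 and Paip1 had log2 fold changes of 0.69, 0.67, 0.48 and 0.53.

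In the lower direction, the genes with the smallest p after Lair1 did not pass either. Prdm16, a zinc finger transcription factor, was at 3.95 ± 1.51 CPM in wild type and 0.803 ± 0.597 CPM in LAIR-1-deficient cells, a log2 fold change of -2.21 (95% interval -3.29 to -1.14). It passed only when no low-count filter was used. Hmox1, the inducible haem oxygenase, was at 5.41 ± 0.722 and 1.96 ± 0.610 CPM, a log2 fold change of -1.48 (-2.21 to -0.75). Zbtb41 was at 7.93 ± 1.37 and 3.94 ± 0.542 CPM. Malat1, an abundant nuclear RNA, was at 474 ± 39.9 and 376 ± 37.0 CPM, and mtNd2, a mitochondrially encoded complex I subunit, at 11670 ± 543 and 9623 ± 585 CPM. Ppt1, Bcap29 and Tspyl2 had log2 fold changes of -0.37, -0.47 and -0.47.

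**Figure D2:**
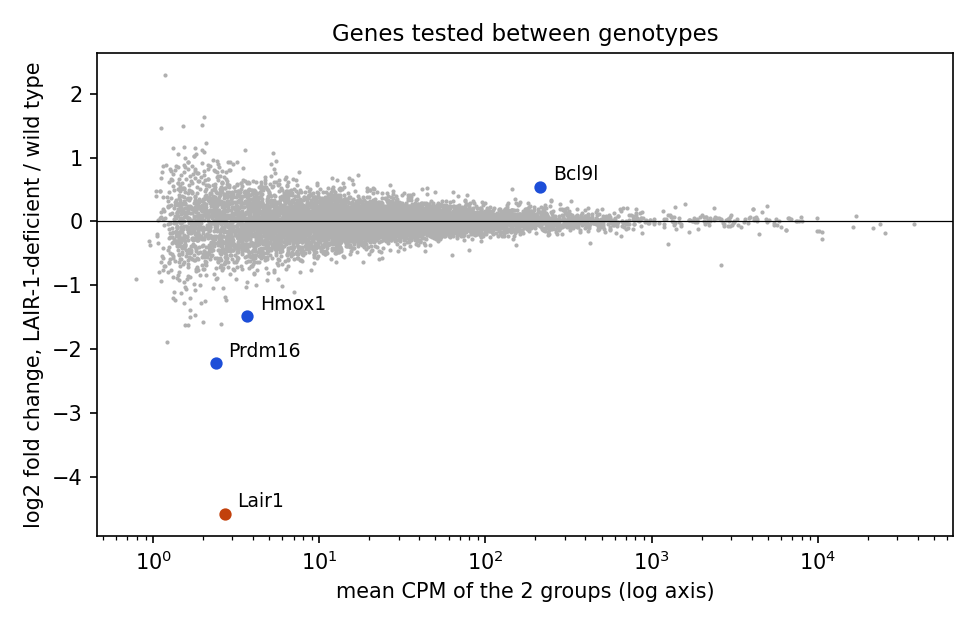
Log2 fold change of LAIR-1-deficient over wild type cells (vertical axis) against the mean CPM of both groups (horizontal log axis) for the 9565 genes tested, each a point. Lair1 (orange, log2 fold change -4.58) was the gene called; Prdm16, Hmox1 and Bcl9l (blue) did not pass the test.

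Intervals derived from the F test bound the size of any difference for most genes. Their coverage was not checked for changed genes alone. The 95% interval of the fold change lay within 2-fold in both directions for 8218 genes (85.9%) and within 1.5-fold for 6046 genes (63.2%). Among the 6620 genes at 10 CPM or more, 98.7% had an interval within 2-fold, against 57.1% of the 2945 genes under 10 CPM. On simulated counts with 200 genes changed per run, a 2-fold change was recovered for 80.9% of changed genes and a 1.5-fold change for 38.2%. At 10 CPM or more these shares were 97.9% and 51.9%. Adjustment by the Benjamini-Hochberg method is stricter where few genes pass, and 1 passed in the real comparison. These shares can therefore overstate recovery there.

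Genes of T cell identity showed no member past the test. Of the 30 measured genes of naive and quiescent T cells, 12 had a positive and 18 a negative fold change, with a list median of -0.03. Myb, a transcription factor of lymphoid progenitors, was at 11.2 ± 2.20 and 16.0 ± 2.82 CPM, and Nsg2 at 264 ± 11.7 and 302 ± 19.4 CPM. Of 18 tested genes of memory and virtual memory cells the median was -0.06; Anxa2 was at 9.76 ± 2.78 and 5.57 ± 2.05 CPM. Of 10 cytotoxic effector genes, 5 were positive and 5 negative. Serpinb9, an inhibitor of granzyme B, was at 17.2 ± 1.64 and 24.7 ± 4.81 CPM, and Cst7 at 62.5 ± 0.0573 and 70.0 ± 8.38 CPM.

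Receptors and signalling genes were likewise without a call. Among 40 genes of the T cell receptor complex and its proximal signalling, 22 were positive and 18 negative with a median of 0.005; the exchange factor Sos1 and the costimulatory receptor Cd28 each had a log2 fold change of 0.31. Inhibitory receptors other than LAIR-1 had 3 positive and 6 negative fold changes over 9 tested genes, with a median of -0.11. Pecam1 was at 131 ± 15.1 and 114 ± 13.2 CPM, and Cd5, a negative regulator of T cell receptor signalling, at 92.0 ± 1.79 and 80.5 ± 11.9 CPM. Among 14 costimulatory receptors the median was -0.02, with Tnfrsf25 at -0.41 and Slamf1 at 0.52. The 25 genes of adhesion, integrins and collagen binding split into 12 positive and 13 negative. Of these, Icam2, a ligand of the integrin LFA-1, was at 51.8 ± 1.64 and 64.7 ± 3.57 CPM, and Itgal, a chain of LFA-1, at 169 ± 21.7 and 200 ± 14.5 CPM. Medians were 0.00 for 17 genes of chemokine receptors and trafficking (Arhgef1 0.15, S1pr4 -0.16) and -0.03 for 31 genes of common gamma chain cytokine signalling (Il6ra -0.22, Gimap6 -0.20). The median was 0.07 for 17 genes of transforming growth factor beta signalling (Tgfbr1 0.33, Ski 0.18). None of the named genes in these groups passed the test.

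Interferon-stimulated genes were the only fixed list called between the genotypes, and the call depended on how the correlation between genes was treated. Of 51 tested genes of the type I interferon response, 42 had a negative and 9 a positive fold change, with a median of -0.20, and 0 passed the test, over all genes or adjusted over the list alone. Irf7, a transcription factor of the response, was at 50.4 ± 12.8 CPM in wild type and 36.5 ± 5.39 CPM in LAIR-1-deficient cells. Ifih1, a sensor of viral RNA, had a log2 fold change of -0.70 (95% interval -1.30 to -0.10). The camera test with a preset correlation of 0.01 gave an adjusted p of 7.50e-05, against an adjusted p of 0.999 with an estimated correlation and 0.889 with fry. The per-library medians, relative to each gene's mean, were -0.20, 0.32 and 0.10 in wild type mice 1 to 3 and -0.21, 0.09 and -0.11 in LAIR-1-deficient mice 1 to 3, so the groups overlapped (two-sided exact permutation p = 0.4, where 0.1 is the smallest possible). Without wild type mouse 2 the camera adjusted p was 0.867 and the list median -0.03, and without LAIR-1-deficient mouse 1 they were 0.122 and -0.10. In the other fits that left out 1 library the list stayed called. The adjusted p lay between 3.91e-16 (without wild type mouse 1) and 0.0138 (without LAIR-1-deficient mouse 3). With an estimated correlation no list was called in any fit that left out a library (smallest adjusted p 0.725). The 29 tested interferon gamma response genes had 13 positive and 16 negative fold changes, with Gbp5 at 0.76 and Gbp9 at -0.31, and an adjusted p of 0.786.

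Genes of proliferation, stress and metabolism gave no list call with TMM scaling, the default count filter and all libraries unblocked. The cell cycle list had 13 positive and 19 negative fold changes over 32 tested genes. Top2a, a topoisomerase of dividing cells, was at 7.28 ± 2.93 and 3.93 ± 0.414 CPM, and Hmgb2 at 55.7 ± 2.49 and 45.8 ± 1.46 CPM. The median was 0.05 for 17 heat shock and chaperone genes, among them Hsph1 (42.0 ± 3.04 and 57.9 ± 19.2 CPM) and Hspa8 (747 ± 58.9 and 856 ± 142 CPM). For 15 genes of the integrated stress response the median was -0.05, with Sdf2l1 at 0.45 and Phgdh at 0.18. Glycolysis genes (21 tested) had a median of 0.03, with Tpi1 at 0.28 and Hk1 at 0.21. The 31 genes of cholesterol and fatty acid synthesis had a median of 0.03, with Mvk at 0.51 and Srebf1 at 0.23. For 21 genes of apoptosis and p53 it was -0.03, with Bcl2l11 at -0.19 and Casp8 at 0.29. Cytosolic ribosomal protein genes split into 56 positive and 26 negative with a median of 0.02. The list was called higher by camera without wild type mouse 1 (adjusted p 0.0361) or LAIR-1-deficient mouse 2 (0.00133), where no list was called with an estimated correlation (smallest adjusted p 0.725 and 0.833). Its camera direction was lower, without a call, without wild type mouse 3 (0.632) or LAIR-1-deficient mouse 1 (0.1199), and without mouse 1 of both groups (0.557). Rps28 was at 4521 ± 12.7 and 5322 ± 374 CPM, and Rpl38 at 2190 ± 67.7 and 2543 ± 116 CPM. The 85 nuclear genes of oxidative phosphorylation had a median of -0.02, with Ndufb5 at 0.34 and Ndufb7 at 0.32. Of 21 tested mitochondrially encoded genes, 17 had a negative fold change with a median of -0.11, and the camera adjusted p was 0.0503, against an adjusted p of 0.999 with an estimated correlation. The call depended on the settings. The adjusted p was 0.0348 when libraries were scaled by their totals, 0.00726 with the stricter count filter, 0.0232 with mouse number as a block, 0.00572 without wild type mouse 1 and 0.00183 without LAIR-1-deficient mouse 2. With an estimated correlation no list was called in these fits, with smallest adjusted p of 0.988, 0.966, 0.98, 0.725 and 0.833. With the preset correlation it was 0.0547 with RLE size factors, 0.6505 without a filter, 0.287 and 0.632 without wild type mouse 2 or 3, and 0.574 and 0.0584 without LAIR-1-deficient mouse 1 or 3. Without mouse 1 of both groups, an alternative chosen after the data were seen, it was 0.158.

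Over the 31 lists with at least 5 tested members, camera called 1 list, and no list was called with an estimated correlation or by fry (smallest adjusted p 0.999 and 0.889). Medians of the 21 functional lists lay between -0.20 and 0.12. No member of any list passed the test over all genes, and 1 passed when adjusted over the list alone, Hmox1 among the macrophage and monocyte genes. The exact permutation p of the list medians was at its smallest possible value of 0.1 for 2 of the 31 lists, adhesion and dendritic cells. Chance alone gives this value for 10% of lists. The median log2 fold change of the adhesion list was -0.002. Median, mean and camera direction did not share a sign for the naive, costimulatory, integrated stress, adhesion, dendritic cell, erythroid, sorting gate, histone and Lair1 neighbour lists.

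Immediate early genes of T cell receptor triggering varied between mice far more than between genotypes. The list medians were 0.69 in wild type mouse 1 and 1.09 in LAIR-1-deficient mouse 1. In mice 2 and 3 they were -0.45 and -0.27 in wild type and -0.56 and -0.43 in LAIR-1-deficient cells. Of 28 tested genes, 24 were higher in both mouse 1 libraries than in all 4 others, and 11 of them by more than 2-fold. Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, was at 473 and 588 CPM in mouse 1 of each genotype and between 56.7 and 113 CPM in the 4 others. Fosb was at 260 and 401 CPM against 29.2 to 74.7 CPM, and Cd69, an early activation marker, at 907 and 973 CPM against 169 to 232 CPM. Nr4a1, Fosb and Cd69 were chosen after their values were seen. Between genotypes, 0 members passed, the camera adjusted p was 0.951, and Tagap and Nab2, the members with the smallest p, had log2 fold changes of 0.57 and -0.13. The direction of the list depended on single libraries. It was called higher without wild type mouse 1 (adjusted p 3.89e-05) or LAIR-1-deficient mouse 2 (0.0133). It was called lower without LAIR-1-deficient mouse 1 (8.85e-10) or without mouse 1 of both groups, an alternative chosen after the data were seen (0.00468). With an estimated correlation, no list was called in these fits, with smallest adjusted p of 0.725, 0.833, 0.872 and 0.729. With the preset correlation, the immediate early list was not called without wild type mouse 2 or 3 (0.225 and 0.718) or LAIR-1-deficient mouse 3 (0.0584).

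**Figure D3:**
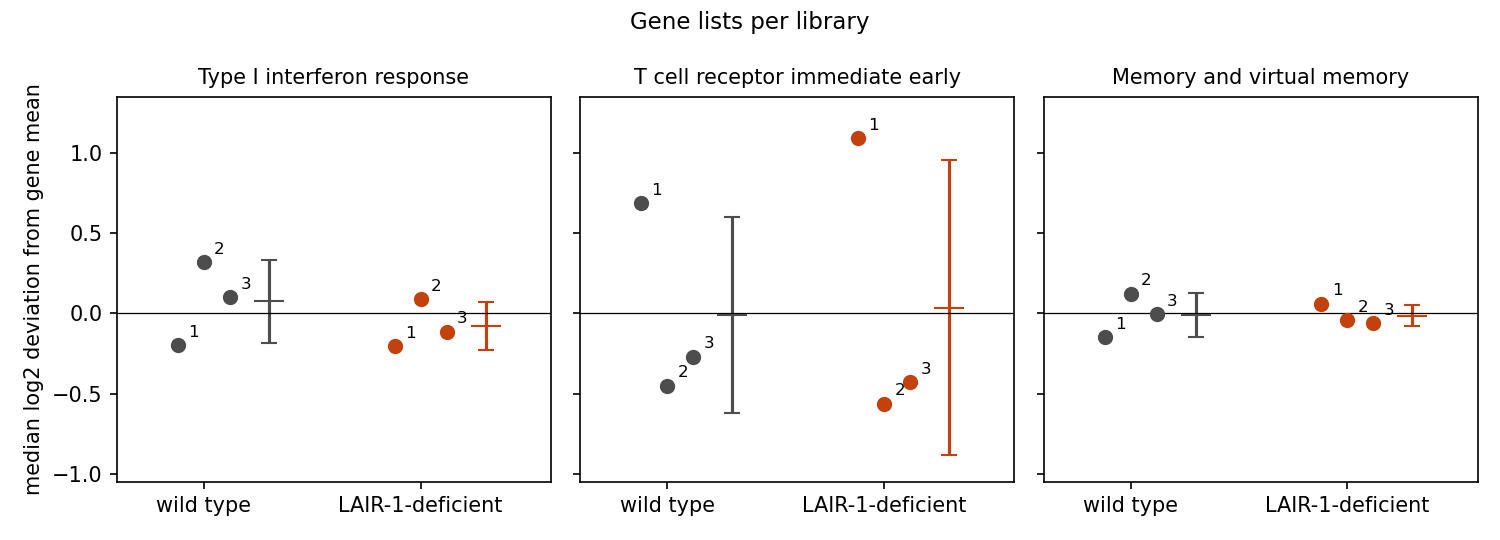
Median log2 deviation of the tested members of 3 gene lists from each gene's mean over the 6 libraries (vertical axis, shared), by library; points are mice, numbered as in the labels, and bars are the mean and SD of 3 libraries. For the immediate early list, mouse 1 of both genotypes lies at 0.69 and 1.09 and the 4 others between -0.56 and -0.27; the memory list lies between -0.15 and 0.12.

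Genes of other cell types were detected in both genotypes, and 0 of them passed the edgeR test over all genes. The 8 tested B cell genes included Cd79b at 14.5 ± 2.45 and 14.8 ± 1.03 CPM and Cd79a at 9.45 ± 2.22 and 7.29 ± 1.73 CPM. MHC class II pathway genes (8 tested) were led by H2-Ob at 121 ± 14.2 and 134 ± 3.09 CPM and H2-DMa at 51.1 ± 1.96 and 56.0 ± 4.16 CPM. Of 16 macrophage and monocyte genes, 11 had a negative fold change (camera adjusted p 0.662), and the list median was 0.33 in wild type mouse 2, 0.14 in wild type mouse 3 and between -0.11 and -0.02 in the other libraries. It included Ctss at 159 ± 16.0 and 144 ± 11.6 CPM and Cst3 at 60.3 ± 7.09 and 59.4 ± 6.90 CPM. The dendritic cell list was led by Ccr9, which naive CD8 T cells also express, at 300.4 ± 42.5 and 296.8 ± 60.3 CPM, followed by Bst2, which is also an interferon-stimulated gene, at 19.4 ± 2.73 and 14.8 ± 1.73 CPM. Folr4 (now Izumo1r) and Gata3 led the list of CD4 and regulatory T cells at 142 ± 10.6 against 128 ± 7.63 CPM and 29.9 ± 2.69 against 30.5 ± 1.93 CPM. List medians of the log2 fold change were 0.21 for B cells (5 positive, 3 negative) and 0.25 for CD4 and regulatory T cells (5 positive, 2 negative). For MHC class II the median was 0.06 (4 positive, 4 negative) and for dendritic cells -0.02 (2 positive, 3 negative). The camera adjusted p was 0.826 for B cells, MHC class II, dendritic cells and CD4 T cells. The erythroid list had an adjusted p of 0.948, with beta globin (Beta-s, now Hbb-bs) at 91.5 ± 67.7 and 66.8 ± 63.3 CPM, highest in wild type mouse 2 at 166 CPM, and Fech at 31.5 ± 8.84 and 34.5 ± 3.04 CPM.

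The remaining cell type lists had fewer than 5 tested members and were not tested as lists. Neutrophil genes were led by G0s2 (3.79 ± 1.21 and 3.85 ± 1.28 CPM) and Cxcr2 (2.57 ± 1.44 and 3.15 ± 0.476 CPM). NK and innate lymphoid genes were led by Il7r, which naive T cells express, at 236 ± 9.74 and 220 ± 22.5 CPM, and Irf8 at 8.10 ± 1.31 and 10.5 ± 6.25 CPM. Plasma cell genes were led by Xbp1 (28.4 ± 8.70 and 29.4 ± 6.56 CPM) and Irf4 (3.87 ± 2.97 and 5.08 ± 5.33 CPM). Irf4 is also in the immediate early list, and both genes were highest in the mouse 1 libraries. Xbp1 was at 38.3 and 36.9 CPM there against 22.4 to 26.1 CPM in the others, and Irf4 at 6.68 and 11.2 CPM against 0.766 to 4.15 CPM. Of stromal and endothelial genes Pecam1 alone was tested. Gamma delta T cell and platelet genes had no tested member. Blk was at 0.591 ± 0.278 and 1.21 ± 0.644 CPM, Sox13 at 0.148 ± 0.128 CPM in wild type with 0 counts in LAIR-1-deficient libraries, Ppbp at 1.91 ± 1.39 and 0.847 ± 0.151 CPM and Pf4 at 1.29 ± 0.527 and 0.858 ± 0.687 CPM.

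Shares of library counts are given with two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3 and so cannot pass the threshold or show similarity. Mitochondrially encoded genes took 19.2 ± 1.96% of counts in wild type and 18.0 ± 2.11% in LAIR-1-deficient libraries (exact permutation p = 0.5), and ribosomal protein genes 24.1 ± 1.29% and 24.7 ± 1.42% (exact permutation p = 0.7). The 10 most abundant genes took 18.9 ± 1.65% and 18.0 ± 1.53% (exact permutation p = 0.5). The haemoglobin share, counted from beta-type globin genes only (mainly Beta-s) and without alpha globin, was 0.00911 ± 0.00673% and 0.00670 ± 0.00633% (exact permutation p = 0.5). The share of Malat1, added to the planned shares, was 0.0472 and 0.0377% and did not overlap between groups (exact permutation p = 0.1). The 13 tested replication-dependent histone genes had a median log2 fold change of 0.01 and a camera adjusted p of 0.999. The X-inactivation gene Xist was found in all 6 libraries at 35.0 to 75.1 CPM. The Y-linked gene Ddx3y had a level of 0.109 CPM in wild type mouse 2 and 0 in the other libraries.

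Genes around Lair1 were examined because a targeted allele can carry linked sequence of another strain. Of 44 tested genes within 5 Mb of Lair1 on chromosome 7, 0 passed the edgeR test. DESeq2 called Lair1 alone, and limma-voom called no gene. By edgeR, 3 of the 44 had an unadjusted p under 0.05, against 307 of 9520 other genes (Fisher's exact test, two-sided p = 0.17). The 3 genes, named after their values were seen, were Eps8l1 (4460674 to 4480487; 3.77 ± 0.773 and 7.24 ± 2.44 CPM), Tmem86b (4628040 to 4631422; 3.37 ± 1.23 and 7.09 ± 3.17 CPM) and Zfp444 (46.9 ± 7.38 and 57.0 ± 5.32 CPM). As a list, the neighbours had a median of -0.01 and a camera adjusted p of 0.868. Windows of 1 and 20 Mb held 2 of 32 and 6 of 109 genes at an unadjusted p under 0.05 (Fisher's exact test, p = 0.278 and 0.169).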

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

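Lair1 was lower in every fit that tested it, and RLE, upper quartile and library-total scaling, DESeq2, edgeR without robust estimation, the replicate block and leaving out mitochondrially encoded genes called Lair1 and no other gene. Without a filter, 1 gene was called higher (Bcl9l) and 2 lower (Prdm16, Lair1). With a smallest count of 50, 0 were called lower, because Lair1 was filtered out. limma-voom, limma-voom with quality weights and the fit without mouse 1 of both groups, which was chosen after the data were seen, called 0 lower. There the log2 fold change of Lair1 was -4.197 (adjusted p 0.1421), -4.107 (0.1478) and -4.614 (0.07122); the last fit had 2 libraries per group, and the cause in the others was not tested. Leaving out each library in turn gave 0 to 1 gene higher (Bcl9l without LAIR-1-deficient mouse 3), 0 to 2 lower and a log2 fold change of Lair1 from -4.932 to -4.262. Without wild type mouse 1 none was lower (Lair1 adjusted p 0.05924), and without LAIR-1-deficient mouse 2 they were Tcf7l1 and Lair1.

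Lists depended more on the settings. The number called was 0 with an estimated correlation and with fry, where the type I interferon list had adjusted p of 0.9989 and 0.8894. It was 2 with library totals, a smallest count of 50 and the replicate block (the interferon and mitochondrially encoded lists), 2 without mouse 1 of both groups (the interferon and immediate early lists), and 0 to 5 when leaving out each library. It was 0 without wild type mouse 2, 5 without wild type mouse 1 and 4 without LAIR-1-deficient mouse 2. The latter fits added immediate early, mitochondrially encoded and cytosolic ribosomal protein lists and, without wild type mouse 1, the macrophage list (adjusted p 0.0412). The adjusted p of the interferon list ranged from 3.908e-16 to 0.8666. With an estimated correlation no list was called in any of these 12 fits (smallest adjusted p 0.725). Mice of the same number correlated by 0.29, 0.01 and 0.07 in their deviations from the group means, so the numbers were not taken to pair the mice. With the number as a replicate block, 0 genes were called higher and 1 lower, and 448 had an unadjusted p under 0.05.

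Some named genes, none of them called, changed sign in some fits. With quality weights, Cd79b was at -0.06194, Gata3 at -0.03547 and Irf8 at -0.001272. Without mouse 1 of both groups, Nab2 was at 0.002693, Cd79b -0.1192, Cst3 0.004159, Ccr9 0.01053, G0s2 -0.05365, Gata3 -0.04114, Irf8 -0.2462, Fech -0.04321 and Irf4 -0.2884. Leaving out each library, log2 fold changes ranged from -0.1429 to 0.07981 for Ptprc, -0.1636 to 0.101 for Cd3e, -0.0908 to 0.03656 for Cd3d and -0.02115 to 0.07243 for Cd8a. They ranged from -0.07233 to 0.1681 for Cd79b, -0.113 to 0.05753 for Cst3, -0.1707 to 0.1212 for Ccr9, -0.2936 to 0.1833 for G0s2 and -0.1028 to 0.7067 for Cxcr2. For Gata3 the range was -0.02714 to 0.1033, for Irf8 -0.2228 to 0.6491, for Beta-s -1.594 to 0.3093, for Xbp1 -0.1488 to 0.3307 and for Irf4 -0.9261 to 1.065. Of 31 list medians, 24 changed sign in at least 1 fit that left out a library, among them transforming growth factor beta signalling (-0.0598 to 0.142), and 13 in another alternative; 5 kept their sign in all fits. Depth limits genes under 10 CPM, where 57.1% had an interval within 2-fold.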

Other observations

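The test with an estimated correlation and the fits that leave out a library were planned; the other tests of explanations below were chosen after the results were seen.

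The type I interferon list lay lower in LAIR-1-deficient libraries by camera with a preset correlation, with 42 of 51 genes negative. A candidate explanation is that these genes vary together between mice: their estimated correlation was 0.542, and with it the adjusted p was 0.9989. Another is the library of wild type mouse 2, which had the highest median (0.32) and also the highest median of the macrophage and monocyte list (0.33): without it the adjusted p was 0.8666 and the list median went from -0.20 to -0.03. Without LAIR-1-deficient mouse 1 the adjusted p was 0.122, while over all fits that leave out a library it ranged from 3.908e-16 to 0.8666. An effect of genotype on interferon signalling stays open. Of the 10 splits of the 6 libraries into 3 and 3, 6, the real one included, gave a camera p as small as the real 2.42e-06. The smallest camera p among the others was 1.777e-24, and 10 splits are too few for a share under 0.05.

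Immediate early genes such as Nr4a1, Fosb and Cd69 were high in mouse 1 of both genotypes, with list medians of 0.69 and 1.09. Depth does not account for this: the 4 other libraries, which include both shallower and deeper ones, had medians of at most -0.27, with an SD of 0.121 among them. More memory T cells, which the CD44 gate would remove, are argued against for wild type mouse 1, which had the lowest memory list median (-0.15). For LAIR-1-deficient mouse 1 they stay open. Its median was 0.0603, against -0.06 to 0.12 in the 4 others, and its Cd44 level was the highest (21.8 CPM, against 11.2 to 14.8 CPM in all other libraries). Ccl5, abundant in memory cells, was at most at 11.5 CPM in the mouse 1 libraries against 13.2 to 20.7 CPM in the 4 others. In contrast, 3 of 18 memory genes (Il2rb, Il18r1 and Ahnak) were higher in both mouse 1 libraries than in all others. Ccl5, Il2rb, Il18r1 and Ahnak were chosen after their values were seen. Handling shared by mice with the same number, such as a day or a place in the sorting order, may have contributed but cannot be told apart from differences between these mice, since the 2 libraries correlated by 0.29 and the labels give no day or order; no biological explanation other than memory cells was tested.

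The mouse 1 libraries also stood apart beyond immediate early genes. Of 31 tested lists, both had medians above all other libraries for 11, among them MHC class II (0.16 and 0.24), the integrated stress response (0.17 and 0.16) and B cells (0.12 and 0.07), and below all others for 3, the type I interferon, cell cycle and mitochondrially encoded lists. The other splits regroup the same libraries in which the mouse 1 pair was singled out. They are therefore no independent evidence that this pair stands apart. The list calls of all splits are from camera with the preset correlation. Of the splits, only the real one was also tested with an estimated correlation, where no list was called. The 4 splits that put both mouse 1 libraries on the same side called 5 to 10 lists and 495 to 1042 genes at an unadjusted p under 0.05, and the 6 splits that part them, the real one among them, called 1 to 2 lists and 218 to 439 genes. All 10 splits called at least 1 list, and the highest other called 10. The list called was not always the interferon list of the real split, whose camera p was 0.207, 0.7787 and 0.9373 in some others. For genes, 3 of the 10 splits, the real one included, called at least 1 gene, and the highest other called 2 (Eif4ebp2 and Iba57). With 10 splits no share can be under 0.05.

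Linked sequence of another strain could raise or lower genes near Lair1, and Eps8l1 and Tmem86b, within 1 Mb of it, had log2 fold changes of 0.95 and 1.08 without passing the test. Within 5 Mb, 6.82% of genes had an unadjusted p under 0.05 against 3.23% of the other genes (Fisher's exact test, p = 0.17). With 1.42 genes expected among 44, the counts are too few to decide, and the strain background of the allele is not given in the labels.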
